A study of Mus musculus with 9 samples.

How the data were processed

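The values used are a table of TPM that the authors deposited, with 1 column per library and genes named by symbol only. The file is named for FPKM, but each column sums to 1000000, so the unit was taken as TPM. The design fixed before the data were examined assumed FPKM; the test was kept the same. Per the submitters' processing notes, Trim Galore 0.5.0, Salmon and the GRCm39 mouse genome were used; the annotation is not given in the sources used here. Per the labels, RNA was isolated with an RNeasy Mini kit, checked on an Agilent Bioanalyzer and sequenced on an Illumina NextSeq instrument. The labels call the cells "PAS-T cells" in 8 libraries, a term they leave undefined, and OVA-stimulated T cells in OVA plus citraconate replicate 1.

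Of the 48709 symbols, 46370 are in GENCODE M21, an annotation of an older mouse build than the one the notes name, so no coordinates are given. Another 238 symbols carry a number that marks a repeated name. For each library a read count per gene was worked back from the table. All 16734 genes above 0 in at least 2 libraries (100%) gave whole numbers. The tolerance was 0.0001 reads or 3e-08 of the count, whichever was larger. On simulated tables the same steps returned 99.8% of 11827 genes. The whole numbers leave open whether Salmon or another counter made the deposited values. How reads of near-identical genes were divided is therefore not known. These recovered reads were used for depth and for the spread between replicates. In 1 alternative they took the place of TPM in the limma fit, with voom weights. The edgeR count test was not run, since the table itself holds no counts.

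Values were changed to log2(TPM + 1). Genes with a mean of at least 1 TPM in any group were tested, 11971 in all. All 9 libraries were fitted together with limma (lmFit, then eBayes with a trend), and the 3 comparisons were OVA against control, OVA plus citraconate against OVA, and OVA plus citraconate against control. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over the tested genes of each comparison; a gene was called at an adjusted p under 0.05. These choices, the 20 alternative settings, the gene lists and the rule for naming genes were made before the data were examined. No further scaling was applied, and the median of ratios (each library scaled by its median ratio to the gene-wise geometric mean) was an alternative.

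The rule named, for OVA against control and for OVA plus citraconate against OVA, the 8 largest increases and the 8 largest decreases. They had to pass the test, have groups that did not overlap and reach 5 TPM in the higher group. Predicted genes, clones, pseudogenes, receptor segments and numbered copies were passed over. Some genes that the rule or the lists hold are not reported here. Added to these were a panel of 12 T cell genes and up to 4 genes per list, those with the smallest adjusted p or, for cell type markers, the highest mean. Genes that went against the rest of their list, genes lying above or below both other groups, the proteases outside the granzymes and the T cell receptor genes were chosen after the values were seen.

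The 25 lists were written from general knowledge and hold 685 entries, of which 675 are in the table, 8 of them under older symbols. They cover stem and memory genes, exhaustion, effector function, T cell receptor activation, the cell cycle, NRF2 targets, interferon, glycolysis, oxidative phosphorylation, the TCA cycle, fatty acid oxidation and cholesterol synthesis. Others cover integrated stress, unfolded proteins, p53, receptors, mitochondrially encoded and ribosomal protein genes. A further 7 hold markers of T cells, CD4 and regulatory T cells, B cells, myeloid cells, natural killer cells, erythroid cells and platelets, and stromal and epithelial cells. Lists with at least 3 tested genes were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01. The adjusted p with a correlation estimated from the data is given beside it, over 24 lists. The fry test in limma asks whether the genes of a list move one way on balance and does not compare them with other genes.

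The steps were tested on simulated data with 200 changed genes of 11971 and the spread of these replicates. The changed genes were not drawn from the lowest-valued genes tested, so the rates of genes found do not cover those. Far fewer genes changed in the simulations than were called in the real data, so the false call rates may differ there. For OVA against control, 79.1%, 88.1% and 100% of genes changed 1.5-, 2- and 4-fold were found, with 10 false calls (5.32%). For OVA plus citraconate against OVA the values were 82.1%, 89.6% and 100%, with 12 false calls (6.22%), and against control 76.1%, 92.5% and 98.5%, with 9 (4.81%). A list of 30 genes shifted by a log2 of 0.50 was called, and 0 of 19 lists left alone were. Each gene was simulated on its own, so this does not test false calls for lists whose genes vary together. In the real data the estimated correlation reached 0.816, for cell cycle genes. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.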

Results

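RNA was sequenced from 9 libraries of mouse CD8+ T cells, the lymphocytes that kill cells presenting a foreign peptide. The labels form 3 groups of 3 libraries: control cells without peptide, cells given OVA peptide, and cells given OVA peptide plus citraconate. OVA peptide is a fragment of chicken ovalbumin that serves as a model antigen, and citraconate is a small unsaturated dicarboxylate, an isomer of itaconate. The title and the design text of the series name as its questions what citraconate does to gene expression in these cells and whether stem-like features are kept. Doses and times are not given in the sources used here. No group had citraconate without peptide, so whether the effect of citraconate depends on the peptide was not tested. The labels do not say whether the replicates are separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

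Values are in TPM, the number of transcripts of a gene per fixed total of transcripts in its library, and are given as mean ± SD over the 3 libraries of a group. The table held 48709 genes, of which 18347 were above 0 in any library and 14537 to 15111 in each library. Reads assigned to genes, recovered from the table, numbered 14754470 to 17384330 per library. Granzyme genes took 0.995% of all transcripts in control, 8.53% with OVA and 3.80% with OVA plus citraconate. Ribosomal protein genes took 19.5%, 15.1% and 17.0%, and mitochondrially encoded genes 7.53%, 7.59% and 9.83%, in the same order. The first principal component held 68.7% of the variance and ordered the groups as control, OVA plus citraconate, OVA. The second held 23.97% and set the citraconate libraries (scores -41.5 to -33.7) apart from the control (12.6 to 14.5) and OVA libraries (13.7 to 38.0). Within groups, OVA replicate 2 and OVA plus citraconate replicate 2 stood farthest from their partners.

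The comparison of OVA with control asks what the peptide changed. Control libraries already held Gzmb (granzyme B) at 7088 to 8199 TPM, Myc at 645 to 658 TPM and the cell cycle gene Top2a at 287 to 330 TPM. The controls can therefore not be taken as resting cells, and rises and falls with OVA are relative to them. With OVA the transcripts of granzymes, the serine proteases of cytotoxic granules, rose by the largest amounts of the genes named. Gzmd rose from 4.91 ± 1.86 TPM in control to 18129 ± 3423 TPM with OVA (SD, n = 3), Gzme from 1.22 ± 0.748 to 7880.1 ± 1427 TPM, and Gzmg from 8.43 ± 4.88 to 12503 ± 2486 TPM. Cxcr4, the receptor for CXCL12, fell from 109 ± 10.2 to 1.78 ± 0.216 TPM. S1pr1, the sphingosine phosphate receptor used to leave lymph nodes, fell from 87.4 ± 7.04 to 1.53 ± 1.15 TPM. Tcf7, which encodes the stem-like T cell factor TCF-1, fell from 61.0 ± 19.1 to 3.24 ± 2.32 TPM.

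Of 11971 genes tested with limma, 8602 passed an adjusted p of 0.05, 3837 higher and 4765 lower with OVA. With scaling by the median of ratios the split was 4406 higher and 4288 lower. At least a 2-fold change was seen for 1054 genes up and 1524 down. For 8981 genes (75.0%) the values of the groups did not overlap, against 10% by chance for 3 libraries against 3. By the naming rule, the genes with the largest increases also included Tyrobp, the adaptor of activating natural killer receptors (0.864 ± 0.189 to 789 ± 179 TPM), and Klrg1, an inhibitory receptor of late effector cells (0.265 ± 0.0733 to 442 ± 76.8 TPM). Spp1, which encodes the secreted protein osteopontin, rose from 15.1 ± 1.25 to 6515 ± 1548 TPM, and Avil, which encodes the actin-binding protein advillin, from 0.171 ± 0.0692 to 336 ± 74.7 TPM. Gzmf rose from 1.56 ± 0.675 to 1084 ± 89.6 TPM. Gzmd, Gzme, Gzmf and Gzmg are near-identical copies, so the division of reads among them is uncertain. Among the largest decreases were Pygl, the liver form of glycogen phosphorylase (97.6 ± 4.14 to 0.418 ± 0.204 TPM), Selenbp1 (63.1 ± 10.04 to 0.112 ± 0.0419 TPM), and Trat1, a T cell receptor-associated adaptor (64.4 ± 5.68 to 0.586 ± 0.336 TPM). Endou, Itga7 and Rcn3 completed the 8 largest decreases, with log2 changes of -5.13, -5.12 and -5.02.

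Effector genes rose as a group: 23 of 31 tested genes rose, 2 fell and 6 did not pass, with a median log2 change of 2.05 (camera adjusted p = 1.32e-07, adjusted p = 0.310 with an estimated correlation). Prf1, which encodes the pore-forming protein perforin, rose from 28.2 ± 2.59 to 5047 ± 935 TPM, Ifng from 79.0 ± 9.35 to 842 ± 262 TPM, and Gzmb from 7702 ± 565 to 19445 ± 629.9 TPM. Serpinb9, the inhibitor of granzyme B, rose from 12.2 ± 0.837 to 276 ± 9.44 TPM. The effector genes that fell were Lta and Tbx21. In the exhaustion list 15 of 28 tested genes rose, 10 fell and 3 did not pass, with a median of 0.42 (camera adjusted p = 0.0442, adjusted p = 0.454 with an estimated correlation). This call was lost under several settings, among them scaling by the median of ratios (adjusted p = 0.101), quantile normalization (0.113), and leaving out OVA replicate 1 (0.0501) or OVA replicate 3 (0.0662). The inhibitory receptor genes in it went different ways: Havcr2 (TIM-3) rose from 20.8 ± 3.67 to 504 ± 49.7 TPM and Pdcd1 (PD-1) from 38.3 ± 6.35 to 148 ± 45.0 TPM. Lag3 fell from 225 ± 16.3 to 147 ± 52.3 TPM and Ctla4 from 248 ± 6.37 to 80.0 ± 24.3 TPM. Tox, a transcription factor of exhausted T cells, did not change past the test (1.26 ± 0.559 and 0.980 ± 0.722 TPM, adjusted p = 0.470).

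Stem and memory genes went down: 3 of 31 tested genes rose, 21 fell and 7 did not pass, with a median of -1.25 (camera adjusted p = 0.00152, adjusted p = 0.454 with an estimated correlation). Klf2, a transcription factor that keeps S1pr1 on, fell from 143 ± 14.8 to 19.3 ± 0.812 TPM, and Bcl2 from 125 ± 5.24 to 27.5 ± 2.28 TPM. Il7r fell from 81.5 ± 3.22 to 18.8 ± 7.06 TPM and Slamf6 from 7.56 ± 1.198 to 0.376 ± 0.0804 TPM. Ccr7, the lymph node homing receptor, did not change past the test (44.0 ± 13.5 and 43.9 ± 22.1 TPM, adjusted p = 0.812). Myb, Il2rb and Cd55 rose, against the rest of the list. Among chemokine, cytokine and adhesion receptors 6 of 29 tested genes rose, 18 fell and 5 did not pass, with a median of -0.71 (camera adjusted p = 0.0294, adjusted p = 0.454 with an estimated correlation). Itgb7 fell from 922 ± 33.97 to 46.4 ± 6.70 TPM, whereas Itga1, an integrin of tissue-resident T cells, rose from 2.0 ± 0.479 to 34.1 ± 8.90 TPM. The T cell receptor activation list was mixed, with 8 of 33 genes higher and 13 lower (camera adjusted p = 0.737, adjusted p = 0.876 with an estimated correlation). In it Myc fell from 652 ± 6.45 to 152 ± 29.8 TPM and Tnfrsf9 (4-1BB) rose from 308 ± 24.3 to 1438 ± 154 TPM.

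Cell cycle genes fell almost without exception: 1 of 41 tested genes rose, 40 fell and 0 did not pass, with a median of -1.001 (camera adjusted p = 1.199e-08, adjusted p = 0.454 with an estimated correlation). Top2a went from 302 ± 23.9 to 101 ± 14.3 TPM and Foxm1 from 75.7 ± 4.85 to 20.6 ± 5.19 TPM; Ccne1 was the member that rose. In the glycolysis list 1 of 30 tested genes rose, 26 fell and 3 did not pass (camera adjusted p = 1.32e-07, adjusted p = 0.454 with an estimated correlation). Egln3, an oxygen sensor, fell from 272 ± 12.3 to 22.7 ± 5.05 TPM and the glucose transporter gene Slc2a3 from 245 ± 9.01 to 77.3 ± 6.61 TPM; the lactate transporter gene Slc16a1 rose. Of the ribosomal protein genes 42 of 46 fell, with a median of -0.44 (camera adjusted p = 1.32e-07, adjusted p = 0.454 with an estimated correlation), and Rpl27 rose. In the interferon list 4 of 29 tested genes rose, 18 fell and 7 did not pass, with a median of -0.79 (camera adjusted p = 0.00810, adjusted p = 0.310 with an estimated correlation). Oas3 fell from 49.1 ± 4.29 to 2.47 ± 1.31 TPM, whereas Isg15, Oasl1, Usp18 and Ifih1 rose.

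Stress genes rose. In the integrated stress and amino acid list 27 of 33 tested genes rose, 5 fell and 1 did not pass, with a median of 0.88 (camera adjusted p = 3.79e-07, adjusted p = 0.454 with an estimated correlation). Asns (asparagine synthetase) went from 55.0 ± 2.81 to 223 ± 20.4 TPM, and Cth, of the cysteine pathway, from 0.201 ± 0.174 to 20.1 ± 1.14 TPM. Slc38a2, Vldlr, Ddit4, Stc2 and Cebpb fell. For unfolded protein and heat shock genes, 20 of 24 tested genes rose, 1 fell and 3 did not pass, with a median of 0.95 (camera adjusted p = 4.06e-07, adjusted p = 0.310 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 393 ± 9.79 to 1182 ± 133 TPM; Dnajb1 fell. Cholesterol synthesis (14 of 25 up, 6 down; camera adjusted p = 0.0271, adjusted p = 0.454 with an estimated correlation) was also called higher. So was the TCA cycle (14 of 28 up, 5 down; camera adjusted p = 0.0197, adjusted p = 0.454 with an estimated correlation). Hmgcs1 rose from 156 ± 1.82 to 399 ± 54.5 TPM and Mdh2 from 299 ± 6.90 to 490.0 ± 19.5 TPM, whereas Idh2 was among the members that fell. NRF2 targets were not called as a list (15 of 27 up, 9 down; camera adjusted p = 0.222, adjusted p = 0.456 with an estimated correlation). Even so, Hmox1 rose from 14.9 ± 1.86 to 109 ± 21.9 TPM and Ftl1 from 1169 ± 27.0 to 6727 ± 1272 TPM. The p53 and apoptosis list (14 up, 7 down of 27; camera adjusted p = 0.0503, adjusted p = 0.454 with an estimated correlation) was not called. Fatty acid oxidation (9 up, 7 down of 25; camera adjusted p = 0.570, adjusted p = 0.715 with an estimated correlation) was not called either. The p53 list was called higher under several settings, among them no filter on low values (0.0207) and leaving out control replicate 3 (0.0379), OVA replicate 2 (0.0249), or OVA plus citraconate replicate 1 (0.0419) or 2 (0.0437). Oxidative phosphorylation (20 up, 7 down of 47; camera adjusted p = 0.0776, adjusted p = 0.456 with an estimated correlation) was not called. It was called higher under several settings, among them scaling by the median of ratios (0.0160) and leaving out control replicate 3 (0.0379) or OVA replicate 3 (0.0422). Of 13 mitochondrially encoded genes mt-Cytb rose and mt-Co1 fell (camera adjusted p = 0.593, adjusted p = 0.876 with an estimated correlation). The fall of mt-Co1 (adjusted p = 0.0487) was not called under several settings, among them scaling by the median of ratios and leaving out any 1 of the control replicates, OVA replicate 2 (log2 -0.17) or OVA plus citraconate replicate 3.

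Markers of other cell types were read in the same libraries. All 12 natural killer markers rose, with a median of 4.73 (camera adjusted p = 1.32e-07, adjusted p = 0.310 with an estimated correlation). Of these, 3 (Gzma, Prf1 and Eomes) are also made by T cells and belong to killing programs. Klrb1c (NK1.1) rose from 0.913 ± 0.700 to 57.0 ± 13.1 TPM, and Ncr1 was listed at 0 in control and at 26.3 ± 4.19 TPM with OVA; both were chosen after their values were seen. The Klra family has near-identical copies, so reads of Klra7 (1.55 ± 0.461 to 65.5 ± 10.7 TPM) are uncertain. T cell markers fell, 15 of 17, with a median of -1.39 (camera adjusted p = 4.12e-04, adjusted p = 0.454 with an estimated correlation). Cd3e went from 1405 ± 23.0 to 513 ± 136 TPM and Cd3g from 1523 ± 80.3 to 409.6 ± 117 TPM. Thy1 did not change past the test (2662 ± 57.4 and 2736 ± 34.9 TPM) except with quantile normalization (log2 0.21) or granzymes left out (0.15). B cell markers (2 up, 5 down of 7; camera adjusted p = 0.197, adjusted p = 0.454 with an estimated correlation) were not called, except lower without a filter on low values (0.0329). Ighm fell from 214 ± 15.0 to 28.4 ± 3.53 TPM, and Igkc rose from 16.9 ± 6.95 to 42.1 ± 13.0 TPM. Myeloid and dendritic markers (4 up, 3 down of 11; camera adjusted p = 0.570, adjusted p = 0.598 with an estimated correlation) had a median of -0.25 but a mean of 1.03, the latter from Fcer1g (2.97 ± 0.396 to 933 ± 247 TPM) and Tyrobp. CD4 and regulatory T cell markers (2 up, 4 down of 8; camera adjusted p = 0.470, adjusted p = 0.598 with an estimated correlation) were not called. Nor were stromal and epithelial markers (3 up, 2 down of 5; camera adjusted p = 0.394, adjusted p = 0.456 with an estimated correlation), though Pecam1 rose from 40.6 ± 1.07 to 276 ± 60.9 TPM. The erythroid and platelet list had 2 tested genes, too few for the list test, and Hbb-bt fell.

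Adjusted over the list alone, the counts were the same for all but the unfolded protein list (20 up, 2 down) and the mitochondrially encoded genes (1 up, 0 down). Camera called 14 of 24 lists with a preset correlation of 0.01 and 0 with an estimated one, where 3 had an unadjusted p under 0.05; fry called 22. The log2 changes are on log2(TPM + 1), which understates changes of genes with low values.

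**Figure D1:**
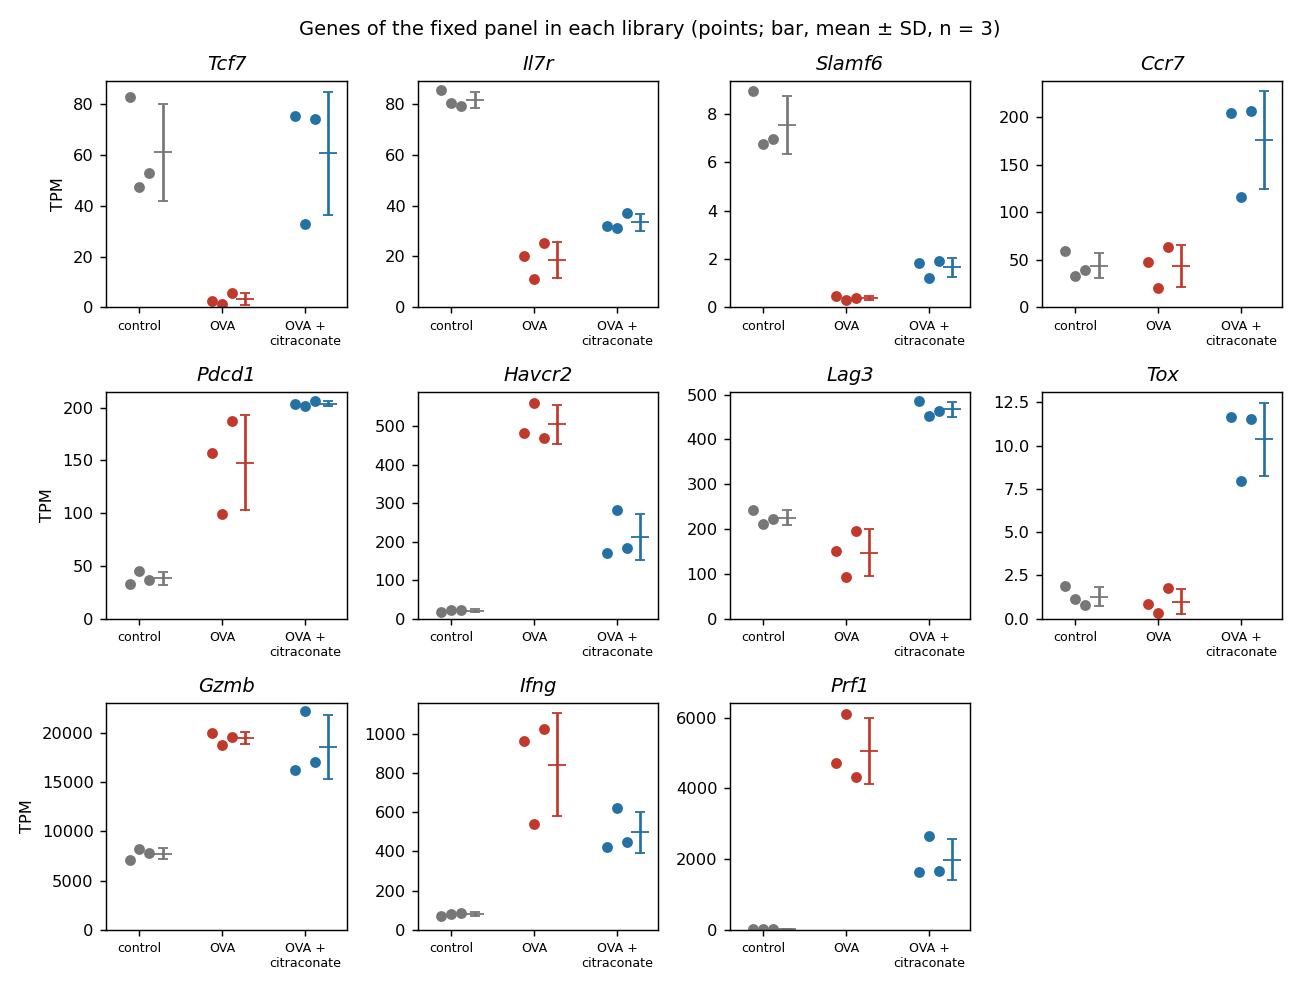
TPM of 11 genes in each of the 9 libraries (points), with mean ± SD per group (bars, n = 3), for control, OVA and OVA plus citraconate. Tcf7 was near 61 TPM in control and with citraconate and at 3.24 TPM with OVA alone.

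The comparison of OVA plus citraconate with OVA asks what citraconate changed in cells given the peptide. Tcf7 rose from 3.24 ± 2.32 TPM with OVA to 60.6 ± 24.2 TPM with OVA plus citraconate (SD, n = 3), beside 61.0 ± 19.1 TPM in control. Id3, a transcriptional inhibitor found in memory T cells, rose from 2.16 ± 1.36 to 23.2 ± 6.24 TPM, and Cxcr4 from 1.78 ± 0.216 to 22.4 ± 4.58 TPM. Gzmg fell from 12503 ± 2486 to 1209 ± 482 TPM, Gzmd from 18129 ± 3423 to 3103 ± 1296 TPM, and Klrg1 from 442 ± 76.8 to 66.4 ± 22.8 TPM. Gzmb was not different past the test (19445 ± 629.9 and 18525 ± 3242 TPM, adjusted p = 0.538 from limma), although it was lower without OVA plus citraconate replicate 2 (log2 -0.22 before the median is taken off).

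With limma, 7065 genes passed, 4522 higher and 2543 lower with citraconate, so that 64.0% of the changes were increases. The median change of all genes was a log2 of 0.12, and with scaling by the median of ratios the split was 3482 higher and 3589 lower (49.2% increases). The log2 changes of this comparison are therefore given relative to that median, except where said. At least a 2-fold change was seen for 924 genes up and 509 down, and for 7915 genes (66.1%) the groups did not overlap, against 10% by chance. Of the genes that the naming rule allows, the largest relative increases were those of Tcf7 (log2 3.78), Cd24a (3.52) and Igfbp7 (3.10). Cd24a, a small surface glycoprotein, went from 2.73 ± 0.745 to 45.4 ± 7.57 TPM, and Igfbp7, a secreted binding protein of growth factors, from 42.7 ± 23.1 to 359.5 ± 36.3 TPM. Nrn1 (neuritin) rose from 128 ± 76.0 to 994 ± 113 TPM, H2-Ab1, an MHC class II chain, from 7.997 ± 3.54 to 72.0 ± 17.1 TPM, and Ifi27l2a from 26.5 ± 18.4 to 191 ± 44.3 TPM. H2 genes have similar copies, so their reads are uncertain. The largest relative decreases, by the same rule, were those of B4galnt2 (-3.998), Ctsg (-3.56), Tmsb15a (-3.56), Itga1 (-3.55), Gzmg (-3.54), Tmem40 (-3.49), Sh2d1b2 (-3.48) and Avil (-3.44). B4galnt2, a glycosyltransferase, went from 33.6 ± 10.2 to 1.37 ± 0.770 TPM, Ctsg (cathepsin G) from 245 ± 8.99 to 21.9 ± 4.03 TPM, and Itga1 from 34.1 ± 8.90 to 2.32 ± 1.16 TPM. Ctsg and Tmsb15a were listed at 0 in control.

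Stem and memory genes rose: 24 of 31 tested genes rose, 3 fell and 4 did not pass, with a median of 1.09 relative to all genes (camera adjusted p = 5.82e-04, adjusted p = 0.633 with an estimated correlation). Ccr7 went from 43.9 ± 22.1 to 176 ± 51.5 TPM, Il7r from 18.8 ± 7.06 to 33.4 ± 3.21 TPM, and Slamf6 from 0.376 ± 0.0804 to 1.66 ± 0.389 TPM. Klf2 rose from 19.3 ± 0.812 to 70.5 ± 11.1 TPM and Foxo1, which drives Klf2 and Il7r, from 10.8 ± 1.84 to 27.2 ± 1.91 TPM. The stem and memory members that fell were Ly6c2 (264 ± 15.9 to 44.1 ± 3.27 TPM, its reads uncertain because of its near copy Ly6c1), Cd55 (56.5 ± 18.4 to 7.26 ± 0.788 TPM) and Il2rb.

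T cell receptor activation genes rose: 26 of 33 tested genes rose, 1 fell and 6 did not pass, with a relative median of 0.90 (camera adjusted p = 1.82e-05, adjusted p = 0.322 with an estimated correlation). Myc went from 152 ± 29.8 to 548 ± 12.2 TPM, Egr2 from 10.7 ± 3.33 to 64.4 ± 9.28 TPM, and Junb from 418 ± 36.2 to 900.3 ± 37.7 TPM; Irf8 fell. In the effector list 14 of 31 tested genes rose, 11 fell and 6 did not pass; its relative median was 0.03 and its relative mean -0.27, and the test pointed down (camera adjusted p = 0.489, adjusted p = 0.814 with an estimated correlation). With scaling by the median of ratios 11 rose and 12 fell. Prf1 fell from 5047 ± 935 to 1986 ± 587 TPM, whereas Tnfsf10 (TRAIL) rose from 20.8 ± 7.13 to 84.0 ± 2.57 TPM and Serpinb6b from 390.0 ± 75.7 to 806 ± 27.4 TPM. Ifng fell from 842 ± 262 to 497 ± 106 TPM, a call that was lost (adjusted p of 0.0629 to 0.0710) without OVA replicate 1 or 3 or OVA plus citraconate replicate 1 or 3. In the exhaustion list 18 of 28 tested genes rose, 5 fell and 5 did not pass, with a relative median of 0.79 (camera adjusted p = 0.0860, adjusted p = 0.633 with an estimated correlation). The list was called higher under several settings, among them scaling by the median of ratios (adjusted p = 0.0169) and leaving out OVA replicate 2 (0.0201). Tox rose from 0.980 ± 0.722 to 10.4 ± 2.11 TPM, Lag3 from 147 ± 52.3 to 467 ± 17.4 TPM and Ctla4 from 80.0 ± 24.3 to 273 ± 12.3 TPM. Havcr2 fell from 504 ± 49.7 to 212 ± 60.7 TPM and Entpd1 (CD39) from 84.2 ± 15.1 to 20.6 ± 5.96 TPM. Pdcd1 was higher with citraconate (148 ± 45.0 and 204 ± 2.31 TPM, adjusted p = 0.0465, log2 0.51 before the median is taken off). That call was lost under several settings, scaling by the median of ratios (adjusted p = 0.116) and quantile normalization (0.0762) among them. It was also lost without any 1 of 7 libraries: control replicates 1 and 3, OVA replicates 1 and 2 (log2 0.24 without the latter, again before the median is taken off), and each citraconate replicate.

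Cell cycle genes rose in part: 35 of 41 tested genes rose, 0 fell and 6 did not pass, with a relative median of 0.49 (camera adjusted p = 7.19e-07, adjusted p = 0.633 with an estimated correlation). Top2a went from 101 ± 14.3 to 194 ± 18.1 TPM and Foxm1 from 20.6 ± 5.19 to 52.9 ± 8.01 TPM. Glycolysis genes (18 of 30 up, 3 down) had a relative median of 0.30 (camera adjusted p = 0.0148, adjusted p = 0.723 with an estimated correlation). Slc2a3 rose from 77.3 ± 6.61 to 179 ± 15.9 TPM, whereas Pfkp, Slc16a1 and Ero1l fell. Of the ribosomal protein genes 31 of 46 were higher, with a relative median of 0.05 (camera adjusted p = 0.00894, adjusted p = 0.746 with an estimated correlation). Scaling by the median of ratios left 5 up and 3 down and ended that call (adjusted p = 0.580), as did leaving out granzymes (0.0726) or OVA replicate 3 (0.0524).

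Stress genes fell. In the integrated stress and amino acid list 2 of 33 tested genes rose, 26 fell and 5 did not pass, with a relative median of -0.84 (camera adjusted p = 5.05e-12, adjusted p = 0.322 with an estimated correlation). Asns went from 223 ± 20.4 to 76.6 ± 5.73 TPM, Nupr1 from 17.6 ± 2.62 to 2.45 ± 0.699 TPM, and Psat1, of serine synthesis, from 216 ± 10.8 to 117 ± 2.40 TPM; Vldlr and Atf3 rose. For unfolded protein and heat shock genes, 1 of 24 tested genes rose, 17 fell and 6 did not pass, with a relative median of -0.55 (camera adjusted p = 7.44e-08, adjusted p = 0.322 with an estimated correlation). Hspa5 fell from 1182 ± 133 to 475 ± 36.0 TPM and Pdia6 from 466 ± 48.7 to 184 ± 11.6 TPM; Dnaja1 rose. NRF2 targets were lower, 15 of 27 with 3 higher and a relative median of -0.30 (camera adjusted p = 1.74e-04, adjusted p = 0.322 with an estimated correlation). Ftl1 (ferritin light chain) went from 6727 ± 1272 to 1786 ± 325 TPM, Hmox1 from 109 ± 21.9 to 25.4 ± 5.28 TPM, and Sqstm1 (p62) from 602 ± 91.5 to 222 ± 32.3 TPM. Nqo1, Gclc and Ephx1 rose, Ephx1 from 5.01 ± 1.84 to 36.1 ± 13.3 TPM. Cholesterol synthesis genes were lower, 11 of 25 with 5 higher (camera adjusted p = 0.00536, adjusted p = 0.633 with an estimated correlation). Hmgcs1 fell from 399 ± 54.5 to 206 ± 10.9 TPM and Acat2 rose from 29.0 ± 0.833 to 43.5 ± 3.18 TPM.

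Several lists of signalling and metabolism were not called. Interferon genes split into 13 up and 9 down of 29 (camera adjusted p = 0.985, adjusted p = 0.986 with an estimated correlation), with a relative median of 0.08 and a relative mean of -0.0019. Gbp2 rose from 21.3 ± 4.23 to 56.2 ± 5.46 TPM, and Isg20 fell from 27.6 ± 2.83 to 8.53 ± 1.25 TPM. The p53 and apoptosis list had 10 up and 9 down (camera adjusted p = 0.730, adjusted p = 0.838 with an estimated correlation); its relative median was -0.02 and its relative mean 0.12, and the test pointed down. In it Bcl2l11, which encodes the death-promoting protein BIM, rose from 6.54 ± 1.23 to 41.9 ± 4.47 TPM and Bid fell from 37.3 ± 5.95 to 11.2 ± 1.28 TPM. Among receptors 17 of 29 tested genes rose, 8 fell and 4 did not pass (camera adjusted p = 0.478, adjusted p = 0.746 with an estimated correlation), and Ccr2 fell from 72.3 ± 4.77 to 22.6 ± 4.41 TPM. Oxidative phosphorylation had 13 up and 9 down of 47 (camera adjusted p = 0.506, adjusted p = 0.814 with an estimated correlation), with a relative median of -0.11. With scaling by the median of ratios it had 5 up and 21 down (adjusted p = 0.0542). Atp5g1, a subunit of ATP synthase, fell from 64.6 ± 4.65 to 34.4 ± 1.35 TPM and Uqcrh rose from 279.9 ± 7.59 to 416 ± 27.99 TPM. The TCA cycle (5 up, 4 down of 28; camera adjusted p = 0.164, adjusted p = 0.746 with an estimated correlation) was called lower with that scaling (2 up, 17 down; adjusted p = 0.00515). Fatty acid oxidation had 7 up and 2 down (camera adjusted p = 0.886, adjusted p = 0.932 with an estimated correlation), with a relative median of -0.10 where the test pointed up. Of the mitochondrially encoded genes 6 of 13 rose (camera adjusted p = 0.206, adjusted p = 0.763 with an estimated correlation), mt-Co1 from 11075 ± 2378 to 18676 ± 2331 TPM. With scaling by the median of ratios 2 rose, and with quantile normalization the list was called higher (adjusted p = 0.0116).

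Natural killer markers fell, 11 of 12, with a relative median of -1.35 (camera adjusted p = 3.43e-06, adjusted p = 0.322 with an estimated correlation). T cell markers rose, 16 of 17, with a relative median of 0.96 (camera adjusted p = 6.79e-05, adjusted p = 0.633 with an estimated correlation). Cd3e went from 513 ± 136 to 1281 ± 84.5 TPM and Gzma from 9087 ± 3067 to 2412 ± 1111 TPM. Myeloid and dendritic markers were not called (4 up, 4 down; camera adjusted p = 0.489, adjusted p = 0.723 with an estimated correlation), with a relative median of -0.16. Fcer1g fell from 933 ± 247 to 134 ± 62.2 TPM, and Cd74 rose from 26.8 ± 14.0 to 65.7 ± 5.02 TPM. B cell markers (1 up, 2 down; camera adjusted p = 0.374, adjusted p = 0.633 with an estimated correlation) included Igkc, which fell from 42.1 ± 13.0 to 0.727 ± 0.378 TPM. CD4 and regulatory markers (4 up, 1 down; camera adjusted p = 0.506, adjusted p = 0.746 with an estimated correlation) were not called. Nor were stromal and epithelial markers (1 up, 2 down; camera adjusted p = 0.267, adjusted p = 0.633 with an estimated correlation), except lower with only the compared groups in the fit (0.0435). Of the erythroid genes Hbb-bt rose. Adjusted over the list alone, the counts changed by at most 2 genes in either direction of any list, as for cell cycle (36 up, 0 down), receptor activation (27 up, 1 down) and oxidative phosphorylation (11 up, 8 down). Camera called 11 of 24 lists with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), and fry called 18.

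**Figure D2:**
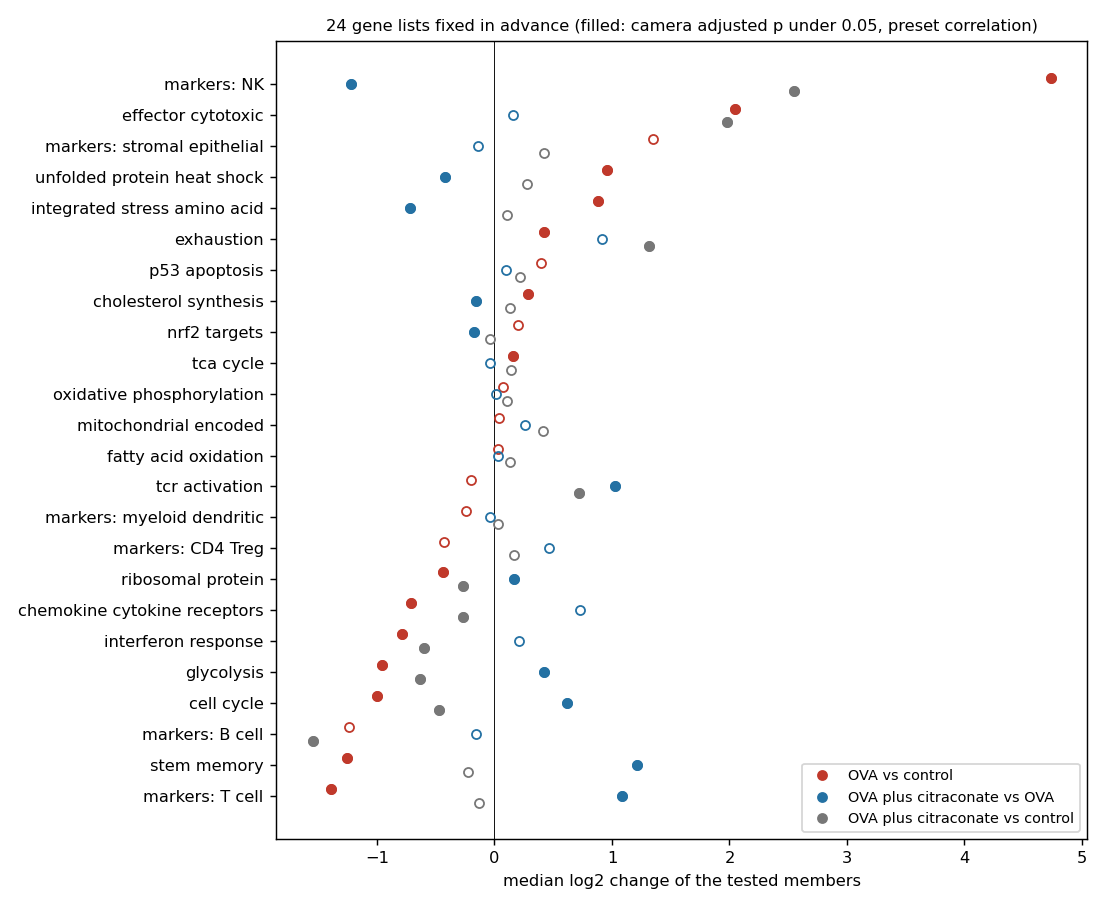
Median log2 change of the tested genes of 24 gene lists (points) in the 3 comparisons, filled where camera called the list with the preset correlation. Stem and memory genes sit at -1.25 for OVA against control and at 1.21 for OVA plus citraconate against OVA, before the median of all genes is taken off.

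The comparison of OVA plus citraconate with control asks how far from control the cells given both stood. The killing genes Prf1, Gzmb and Gzmd were up. Prf1 was at 28.2 ± 2.59 TPM in control and 1986 ± 587 TPM with OVA plus citraconate (SD, n = 3), Gzmb at 7702 ± 565 and 18525 ± 3242 TPM, and Gzmd at 4.91 ± 1.86 and 3103 ± 1296 TPM. Gzma overlapped between the groups, at 1249 to 2043 TPM in control and 1741 to 3695 TPM with OVA plus citraconate. Tcf7 (61.0 ± 19.1 and 60.6 ± 24.2 TPM, adjusted p = 0.904 from limma) did not differ past the test. Ccr7 stood above control, from 44.0 ± 13.5 to 176 ± 51.5 TPM, while Il7r was below it, from 81.5 ± 3.22 to 33.4 ± 3.21 TPM. All of Pdcd1, Havcr2, Lag3, Tox and Ifng rose, and Slamf6 fell to 1.66 ± 0.389 TPM.

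With limma, 7110 genes passed, 3963 higher and 3147 lower (3613 and 3492 with scaling by the median of ratios). At least a 2-fold change was seen for 827 genes up and 696 down, and for 8066 genes (67.4%) the groups did not overlap, against 10% by chance. Effector genes were up (27 of 31, 2 down; camera adjusted p = 7.79e-10, adjusted p = 0.171 with an estimated correlation). So was the exhaustion list (21 of 28, 2 down, median 1.32; camera adjusted p = 6.51e-06, adjusted p = 0.171 with an estimated correlation). Rgs16 rose from 11.3 ± 0.533 to 289 ± 23.8 TPM and Eomes from 3.35 ± 0.171 to 82.8 ± 15.6 TPM; Maf and Cish were the exhaustion genes that fell. Receptor activation genes were up (21 of 33, 1 down; camera adjusted p = 2.94e-04, adjusted p = 0.327 with an estimated correlation). Crtam, an adhesion receptor of cytotoxic T cells, rose from 3.04 ± 0.202 to 306 ± 28.5 TPM, and Cd40lg fell. Natural killer markers were up (10 of 12; camera adjusted p = 1.84e-06, adjusted p = 0.268 with an estimated correlation).

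Lists lower than in control were glycolysis (25 of 30 down, 2 up; camera adjusted p = 3.02e-08, adjusted p = 0.327 with an estimated correlation) and ribosomal proteins (31 of 46 down; camera adjusted p = 3.46e-07, adjusted p = 0.610 with an estimated correlation). Cell cycle genes were lower too (29 of 41 down, 1 up; camera adjusted p = 6.51e-06, adjusted p = 0.638 with an estimated correlation). Aldoa fell from 2549.5 ± 58.8 to 1306 ± 83.7 TPM, Mcm2 from 169 ± 8.86 to 97.1 ± 8.09 TPM and Rps16 from 4215 ± 152 to 2882 ± 124 TPM. Interferon genes were lower (19 of 29 down, 2 up; camera adjusted p = 2.54e-04, adjusted p = 0.171 with an estimated correlation). Receptors (15 of 29 down, 5 up; camera adjusted p = 0.00646, adjusted p = 0.327 with an estimated correlation) and B cell markers (6 of 7 down, 1 up; camera adjusted p = 0.00446, adjusted p = 0.171 with an estimated correlation) were also lower. Isg20 fell from 32.3 ± 1.31 to 8.53 ± 1.25 TPM, Ccr2 from 109 ± 12.5 to 22.6 ± 4.41 TPM and Igkc from 16.9 ± 6.95 to 0.727 ± 0.378 TPM. Genes that went against their lists were Eno2 and Hif1a for glycolysis, Ifih1 and Slfn5 for interferon, Ccne1 for the cell cycle and Ebf1 for B cells. Stem and memory genes were mixed (9 up, 14 down of 31; camera adjusted p = 0.0987, adjusted p = 0.701 with an estimated correlation). So were T cell markers (4 up, 5 down of 17; camera adjusted p = 0.362, adjusted p = 0.826 with an estimated correlation).

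Integrated stress (15 up, 9 down; camera adjusted p = 0.602, adjusted p = 0.868 with an estimated correlation) and p53 (14 up, 4 down; camera adjusted p = 0.0635, adjusted p = 0.473 with an estimated correlation) were not called against control. Nor were unfolded protein genes (14 up, 3 down; camera adjusted p = 0.0635, adjusted p = 0.610 with an estimated correlation). Oxidative phosphorylation (16 up, 2 down; camera adjusted p = 0.0977, adjusted p = 0.638 with an estimated correlation) was not called, nor was the TCA cycle (14 up, 3 down; camera adjusted p = 0.0977, adjusted p = 0.679 with an estimated correlation). Of the mitochondrially encoded genes 9 of 13 rose (camera adjusted p = 0.0635, adjusted p = 0.679 with an estimated correlation), mt-Cytb from 4092 ± 102 to 7988 ± 1419 TPM. Leaving out OVA replicate 2 or OVA plus citraconate replicate 1 made the unfolded protein (0.0453, 0.0345), p53 (0.0453, 0.0345) and mitochondrially encoded lists (0.0167, 0.0205) pass. Without a filter on low values these lists and the TCA cycle (0.0376) and oxidative phosphorylation (0.0366) passed (unfolded protein and p53 0.0163, mitochondrially encoded 0.0380). With quantile normalization unfolded protein (0.0302), p53 (0.0471) and oxidative phosphorylation (0.0468) passed. Oxidative phosphorylation also passed, among other settings, without control replicate 3 (0.0391) or OVA plus citraconate replicate 2 (0.0466). Hspa5 was at 393 ± 9.79 TPM in control and 475 ± 36.0 TPM, Asns at 55.0 ± 2.81 and 76.6 ± 5.73 TPM. NRF2 targets had a median of -0.03 and a mean of 0.01, with the test pointing down (camera adjusted p = 0.362, adjusted p = 0.679 with an estimated correlation). CD4 markers had a median of 0.16 with the test pointing down (camera adjusted p = 0.911, adjusted p = 0.933 with an estimated correlation). Adjusted over the list alone, the counts changed in 5 lists, by 1 gene each: receptor activation (22 up), cell cycle (30 down), fatty acid oxidation (11 up), integrated stress (10 down) and natural killer markers (11 up). Camera called 10 of 24 lists with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05), and fry called 21.

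Seen over both peptide comparisons, genes changed by OVA often changed the opposite way with citraconate. Myc went from 652 ± 6.45 to 152 ± 29.8 and then 548 ± 12.2 TPM, and Cd3e from 1405 ± 23.0 to 513 ± 136 and then 1281 ± 84.5 TPM. In the other direction, Hmox1 went from 14.9 ± 1.86 to 109 ± 21.9 and then 25.4 ± 5.28 TPM, and Itga1 from 2.0 ± 0.479 to 34.1 ± 8.90 and then 2.32 ± 1.16 TPM. Of 8602 genes changed by OVA, 58.7% changed the opposite way with citraconate.

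A total of 5683 genes passed in both comparisons, 5046 of them (88.8%) with opposite signs. Of these, 1933 rose with OVA and fell with citraconate, against 815 if the calls were independent, and 3113 fell and then rose, against 1800. Same-sign changes numbered 434 upward, against 1449, and 203 downward, against 1012. Both comparisons use the same OVA libraries, which by itself gives opposite errors. In simulated data with that sharing and no effects, the correlation of the log2 changes was -0.50 on average (lowest -0.54), beside -0.61 observed. Over all tested genes, 74.6% of the changes had opposite signs, beside 66.7% in the simulated data. The covariance was -0.0125, beside -0.42 observed. Relative to control, 2331 of the 5046 genes no longer differed past the test, 2288 were still on the OVA side and 427 had passed beyond control.

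In all, 1504 genes were higher with OVA plus citraconate than in both other groups, 254 of them at least 2-fold, and 636 were lower, 74 of them at least 2-fold. The 427 genes that had passed beyond control are among these. The genes named here were chosen after the values were seen, from among the 8 in each direction with the largest such changes, and not all of those are named. Above both groups, Igfbp7 was at 3.30 ± 0.757, 42.7 ± 23.1 and 359.5 ± 36.3 TPM in control, OVA and OVA plus citraconate, and Nrn1 at 78.3 ± 2.98, 128 ± 76.0 and 994 ± 113 TPM. Csf2, which encodes the cytokine GM-CSF, was at 9.11 ± 2.25, 42.1 ± 17.8 and 295 ± 112 TPM, and Pacsin1 at 0.904 ± 0.115, 0.830 ± 0.568 and 12.8 ± 2.04 TPM. Below both groups, Ifitm1, an interferon-induced membrane protein, was at 3036 ± 261, 1704 ± 306 and 355 ± 118 TPM, and Ly6c2 at 251 ± 28.01, 264 ± 15.9 and 44.1 ± 3.27 TPM. Acvrl1, a receptor of the TGF-beta family, was at 20.6 ± 3.76, 13.0 ± 7.06 and 0.390 ± 0.382 TPM, and Eya2 at 37.2 ± 1.01, 10.7 ± 1.99 and 2.32 ± 0.398 TPM. With scaling by the median of ratios the groups held 1110 and 936 genes.

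**Figure D3:**
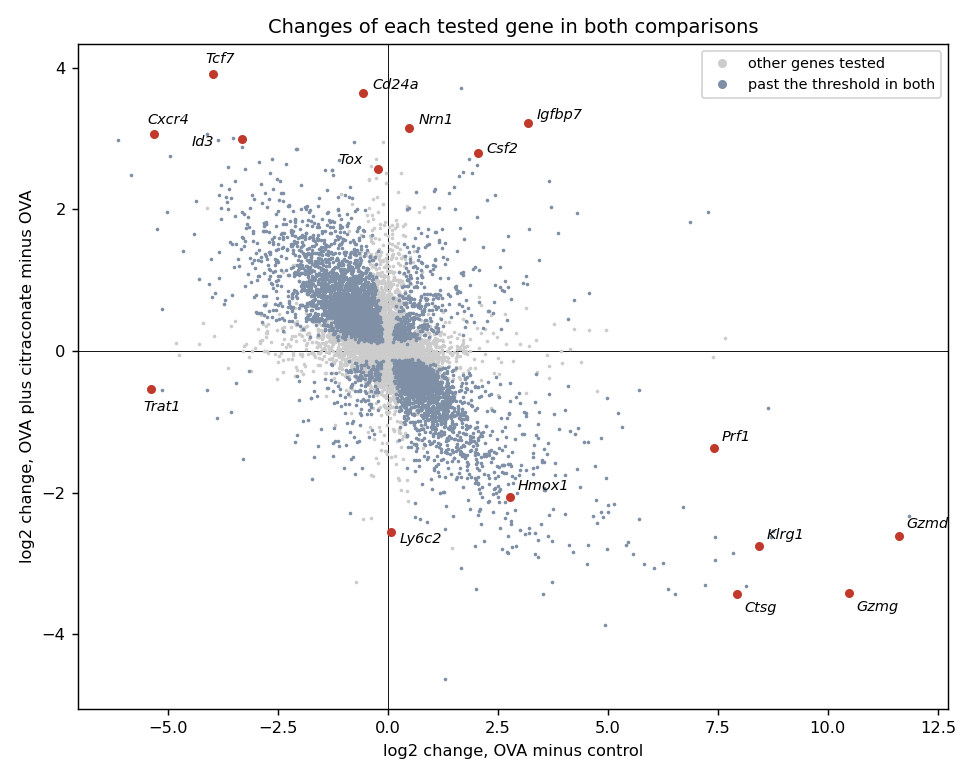
Log2 change of each of the 11971 tested genes with OVA against control (horizontal) and with OVA plus citraconate against OVA (vertical), on log2(TPM + 1) and as deposited, with genes past the threshold in both in blue. Most of the 5683 blue genes lie in the quadrants of opposite sign.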

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

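The 2 alternatives with voom weights on recovered reads and with granzymes left out, and the genes lying outside both other groups, were chosen after seeing the data; the other 20 settings were planned. Alternatives that need a table of counts, or both counts and another unit, were not run.

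The counts of changed genes stayed within 1.5 times those of the report under every other scaling, filter, pseudocount and weighting tried, with 1 exception. Requiring at least a 2-fold change as well left 2578, 1433 and 1523 genes for OVA against control, OVA plus citraconate against OVA, and OVA plus citraconate against control, since it adds a condition. Without a filter the counts were 9209, 7237 and 7410, and with a mean of at least 5 TPM 7236, 6076 and 6075, since fewer genes were tested. Scaling by the median of ratios gave 8694, 7071 and 7105 genes, voom 8633, 7128 and 7249, and granzymes left out 8668, 6988 and 7209. Quantile normalization put 962 genes below both other groups in place of 636, and scaling by the median of ratios put 936 there. Above both groups they left 1146 and 1110 genes in place of 1504. Both removed most of the median log2 change of all genes with OVA plus citraconate, which was 0.12 against OVA and 0.04 against control. The size of the excess of genes above over genes below thus depended on the scaling.

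Leaving out each library in turn gave 8018 to 8629, 6211 to 6953 and 6332 to 7345 changed genes in the same order. Genes with opposite changes numbered 4382 to 5035, genes above both other groups 1178 to 1529, and genes below both 529 to 611. Called lists numbered 13 to 16, 10 to 12 and 10 to 13.

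Called lists depended most on the test. An estimated correlation called 0, 0 and 0 lists in place of 14, 11 and 10. The estimate was far above the preset 0.01 for some lists, such as cell cycle (0.816) and T cell markers (0.725). For the interferon list it was near the preset (0.0115), and that list also lost its call. A higher correlation is therefore not the whole cause. For OVA against control, the interferon list had a camera p before adjustment of 0.00338 with the preset and 0.0278 with the estimate. Adjusted over the 24 lists, the latter became 0.310, so the adjustment took part in the lost call. Why the unadjusted p rose was not tested. The fry test, which does not compare a list with other genes, called 22, 18 and 21.

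Over 215 named genes and all settings, 3979, 3960 and 3956 results kept their direction and their side of the threshold, while 26, 38 and 55 lost a call and 41, 27 and 37 gained one. Another 23, 39 and 19 changed sign without passing the threshold in either fit. Reversed signs were seen with quantile normalization for mt-Atp6 with OVA against control (log2 -0.33 in place of 0.07) and for Thy1 with OVA plus citraconate against control (0.19 in place of -0.02); the cause was not tested. Over the lists, 460, 460 and 455 results were the same in this sense, 20, 14 and 10 lost a call, 22, 16 and 32 gained one, and 1, 13 and 6 changed direction without being called in either.

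The labels number the replicates without saying that equal numbers belong together. Of 9 pairs with equal numbers, 3 correlated best with their own number after group means were removed (-0.01 to 0.30 over all 9). These 3 were the replicate 2 pairs: control with OVA (0.08), OVA with OVA plus citraconate (0.30), and control with OVA plus citraconate (0.10). A factor shared by the replicate 2 libraries is therefore possible and was not tested. With the replicate block the counts were 8578, 7004 and 7128 genes and 14, 11 and 11 lists; Pdcd1 with OVA plus citraconate against OVA had an adjusted p of 0.0532, and the unfolded protein list against control 0.0448.

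At 14754470 to 17384330 recovered reads per library, depth limits what can be said of genes with a few TPM or less; of 48709 genes, 11971 were tested.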

Other observations

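The tests of explanations in this part, the splits among them, were chosen after the results were seen, as were the genes named. The fit with only the compared groups, used for the splits, was a planned setting.

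Some chemokine and receptor genes were also read. Xcl1, which draws cross-presenting dendritic cells, was at 3.46 ± 1.73, 552 ± 286 and 1741 ± 273 TPM in control, OVA and OVA plus citraconate. Ccl5 was at 381 ± 94.4, 556 ± 211 and 1386 ± 535 TPM and Ccl4 at 20.7 ± 4.47, 411 ± 109 and 685 ± 232 TPM. Tigit, an inhibitory receptor gene, was at 119 ± 0.659, 156 ± 44.2 and 474 ± 24.5 TPM, and Nr4a1, an early gene of receptor signalling, at 111 ± 21.7, 15.6 ± 8.54 and 77.4 ± 16.1 TPM.

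Some genes of the T cell receptor and its coreceptor were read too. The coreceptor gene Cd8a was at 217 ± 6.15, 142 ± 37.5 and 325 ± 38.7 TPM and Cd8b1 at 601 ± 14.7, 177 ± 47.8 and 347 ± 31.4 TPM. Of the receptor chains, Trac was at 980.5 ± 26.5, 379 ± 102 and 1047 ± 83.1 TPM, Trbc1 at 589 ± 20.04, 448 ± 47.2 and 721 ± 41.9 TPM, and Trbc2 at 1436 ± 77.3, 1085 ± 193 and 2275 ± 323 TPM. The variable segment Trbv12-1 was at 478 ± 65.9, 719 ± 107 and 1628 ± 188 TPM.

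Proteases of basophils, mast cells and neutrophils rose with OVA: Mcpt8 from 0.120 ± 0.104 to 193 ± 26.5 TPM, Cma1 from 0.188 ± 0.203 to 55.9 ± 10.2 TPM, and Ctsg, listed at 0 in control, to 245 ± 8.99 TPM. Neutrophils in the OVA libraries are argued against by 7 other neutrophil genes, the highest at 0.0295 TPM beside Ctsg. Mast cells or basophils in the OVA libraries stay open. Of 8 other genes of those cells, with a median of 0.307 TPM with OVA, 3 could be tested (Cpa3, Fcer1a and Prss34), and all rose. Fcer1a and Prss34 were listed at 0 in control, so the filter largely fixed their direction. Cpa3 rose from 3.43 ± 1.45 to 7.72 ± 1.97 TPM, though that rise was not called without control replicate 3 (limma adjusted p = 0.0658) or OVA replicate 1 (0.0625). Higher transcription of the gene cluster that holds the granzymes stays open too: the 6 cluster genes with at least 1 TPM in control all rose, but the proteases were lower than that in control, so the filter largely fixed their direction. Reads shared with the granzyme genes of the same family cannot be told apart from these, since 2 of 3 proteases had a ratio to Gzmd that differed between OVA and OVA plus citraconate in all libraries (Ctsg 1.38% and 0.747%, Cma1 0.310% and 0.229%) and Mcpt8 did not (1.07% and 1.02%).

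Natural killer genes rose and T cell genes fell with OVA. A lower share of T cells would lower T cell genes alike, but over 17 genes the log2 changes had an SD of 0.755, beside a median standard error of 0.154, and ran from -2.73 to 0.04. That argues against it as the whole cause. Natural killer cells in the OVA libraries cannot be told apart from T cells that express natural killer receptors: Ncr1 was at 26.3 TPM, a library does not show which cell held it, and no sort is given in the sources used here. A switch of the stimulated T cells themselves may account for the pattern and stays open.

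Changes with citraconate were mostly opposite to those with OVA. The OVA libraries shared by both comparisons give a covariance of -0.0125 on average (lowest -0.0142 in 100 simulated draws), beside -0.42 observed. The covariance beyond that average was -0.41, which argues against sharing as the source of most of it. The 3 OVA libraries cannot be split into parts of at least 2, so separate OVA libraries for each comparison were not tried. A mixture of control-like and OVA-like cells, or a peptide response only smaller in size in every gene, would leave no gene outside both groups. Of the tested genes, 17.9% (2140) lay there, which argues against either as the whole cause. This does not cover a weaker or later response in which genes can pass outside both groups, since doses and times are not given. The share of transcripts taken by granzymes was argued against by 4963 genes with opposite changes when granzymes were left out. An effect of citraconate on the cells beyond a weaker response is a hypothesis that no group here tests on its own.

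Splits of the libraries into other groups of 3 number 10 for each comparison, too few for a share under 0.05. Every other split also mixes the real groups, so the group differences enter its spread and part of them stays in its contrast. The genes and lists called in the other splits are therefore no measure of what libraries without group differences would give. With only the compared groups in the fit, the real split gave 8392, 6621 and 7230 changed genes (highest other 0 in each), so 1 of 10 splits gave as many. The peptide libraries gave 5046 opposite changes, 1504 genes above and 636 below both groups in the real split (highest other 0, 1 of 10 splits). Called lists were 15, 12 and 12, with a highest other of 12, 13 and 11, and 1, 3 and 1 of 10 splits gave as many.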
